A study of Caenorhabditis elegans with 2 samples.

How the data were processed

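The 2 samples are ChIP-seq libraries of tagged NHR-84 from L1 larvae, labelled as biological replicates 1 and 2 of 1 group. Per the labels, chromatin was fragmented by sonication and the antibody is named by its target. The authors deposited lists of regions in narrowPeak format on builds ce10 and ce11. Per the deposited file records, 1 list per replicate and build was made from that replicate alone, 1 list from both replicates pooled, and 1 list passed the IDR threshold, with a control alignment as a parent of the lists. The aligner, the peak caller, their settings and the IDR threshold are not given in the sources used here. The control was not analysed here.

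The deposited signal is the caller's own value per region; its scale is not stated and differs between lists, so it was used only to describe and rank regions within a list. The deposited −log10 q-value comes from the caller too. On ce11 all regions of a list have 1 width, 290 bp in replicate 1 and 304 bp in the other lists. Each of the replicate and pooled lists ends at 30000 regions, at signals of 9.08, 8.96 and 16.2, so these lists include background regions by construction. The lists give no read counts, so depth is unknown and a weaker replicate cannot be told from a shallower one. Wilson intervals and limits for counts of 0 (3 counts of the total) cover counting error over peaks or genes only.

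Regions were annotated on ce11 with the Ensembl 115 gene set, whose assembly is the same as ce11, and no region lay past a chromosome's end. Coordinates on ce10 were neither annotated nor converted. Summits were taken as deposited. A summit from 500 bp upstream to 100 bp downstream of a TSS was counted as at the promoter. A summit within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene was counted as at a short RNA gene. Feature classes were assigned in the order promoter, short RNA gene, 5' UTR, coding exon, 3' UTR, intron, intergenic. Regions of the replicates were matched when their summits lay within 100 bp.

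Shares of IDR peaks were tested with one-sided permutation tests of 100000 draws from the pooled regions below the IDR peaks, drawn per chromosome, or within 5 bins of GC content for sequence words. Gene lists were tested with one-sided Fisher's exact tests against the 9858 genes that had any pooled region in the promoter window, with Benjamini-Hochberg adjustment over 20 lists. The lists were defined by gene names or biotype. The overlap of the replicates' top regions was tested with 1000 draws, and the nhr-84 locus with 10000 random windows. A threshold of 0.05 was used. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

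The tests were checked on simulated data. Of 100 draws of 106 regions with no effect, the promoter test gave p under 0.05 in 3 and the ribosomal protein test in 1, and with 30 promoter or 10 ribosomal peaks planted, both did so in 100 of 100.

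The groups, most tests, the gene lists, the words and most alternatives were fixed before the data were examined. The comparison of promoter shares between X and the autosomes and the test of GC content were not among the planned tests. Genes were named by a rule fixed then: the 20 IDR peaks with the highest signal by nearest coding TSS, up to 4 members per list with a peak at the promoter, and nhr-84. Alternatives were other promoter windows, summit distances and backgrounds, the 53 highest peaks, build ce10 and each replicate alone. With replicate 1 or 2 left out, the 106 highest regions of the other replicate's list took the place of the IDR peaks. Backgrounds of coding genes or of regions down to rank 1000, autosomal peaks only, each ribosomal peak counted once, ribosomal windows in no other gene's window, and the most frequent word of 10 bases in 1000 draws of lower X regions were added after seeing the data.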

Results

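The data are ChIP-seq of NHR-84, a member of the nuclear hormone receptor family of transcription factors, in first-stage (L1) larvae of Caenorhabditis elegans. NHR-84 carried a C-terminal GFP-FLAG tag and was expressed from an integrated transgene, and chromatin came from whole animals of mixed sex. There was 1 group with 2 biological replicates, so no comparison between conditions could be made, and a control library was not analysed here. The values are lists of called regions, 30000 for each replicate and 30000 for the replicates pooled. A shorter list, labelled optimal, holds the peaks that passed the irreproducible discovery rate (IDR) step. That step is meant to keep regions ranked alike in both replicates. The list also held peaks ranked as low as 27977 in replicate 1 and 22319 in replicate 2, so a peak in it need not be strong in both. The lists hold no read counts, so the sequencing depth of each replicate is unknown and the signal values carry no counting error. Coordinates and values are on build ce11 unless another is named.

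The IDR list held 106 peaks, each 304 bp wide. The highest peak lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit, with a caller's signal of 175 against a median of 60.1 over all IDR peaks and 20.4 over all pooled regions. Next came a peak in intergenic sequence on X nearest to W02H3.3 (signal 144), a peak 160 bp upstream of cdc-48.1, an AAA ATPase that acts in protein quality control (140), and a second intergenic X peak nearest to F19H6.5 (122.5). The 106 peaks were exactly the regions of highest signal in the pooled list, down to a signal of 52.0. The q-value deposited with each peak ranged from 0.0182, shared by 28 peaks, to 0.431, so the caller's own q was high for the lower peaks.

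Of the 20 peaks with the highest signal, 4 more lay at ribosomal protein genes: rpl-35 (chromosome III, 7854541 to 7854844, signal 112), rps-19, which shares its upstream sequence with the DNA damage gene hsr-9 (I, 9625918 to 9626221, 103), rpl-20, which shares it with Y17G9B.5 (IV, 4749902 to 4750205, 102), and rpl-15 (IV, 654790 to 655093, 88.2). The rpl-15 peak also lay in the promoter window of K11H12.8. Peaks at the promoters of abhd-5.2 (V, 4844652 to 4844955, 108), tasp-1 (III, 10759047 to 10759350, 98.9) and the translation elongation factor gene eef-1A.2 (X, 7823168 to 7823471, 88.0) were also among the 20. The peak nearest to C34C12.1 (107) lay in a 5' UTR of C34C12.2, and that nearest to W06H8.6 (92.6) lay in an intron of that gene. The peak nearest to nlp-40, a neuropeptide gene, was intergenic, 1950 bp from the TSS (90.3). Peaks nearest to egg-5 (98.3) and ZK1248.17 (89.3) lay on sls-2.4 and sls-2.1, genes for the SL2 spliced leader RNA that is joined to downstream genes of operons. The X peaks nearest to gtr-1 (109), xol-1 (95.5), ZK899.6 (94.9) and K02D3.1 (88.1) were intergenic, between 2522 and 6052 bp from the nearest coding TSS. xol-1 is the switch gene of sex determination and dosage compensation.

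The replicates shared their strongest regions far above chance but ranked most regions differently. Both placed the rpl-3 peak first, with signals of 77.1 in replicate 1 and 98.7 in replicate 2. The cdc-48.1 peak ranked 3 and 4, and the F19H6.5 peak 6 and 5. Others stood high in 1 replicate: abhd-5.2 ranked 2 in replicate 1 and 118 in replicate 2, and the xol-1 peak ranked 181 and 6. Of the 106 regions with the highest signal in replicate 1, 30 (28.3%, 95% Wilson interval 20.6 to 37.5) had a summit within 100 bp of one of the 106 highest in replicate 2. Draws of 106 regions from the whole replicate 2 list gave a mean of 0.283% and at most 2.83% (one-sided permutation p = 0.001, the smallest that 1000 draws can give). With the 1000 highest regions of each list the share was 12.8% against 1.45% (permutation p = 0.001).

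Of the IDR peaks, 98 had a region within 100 bp in replicate 1 and 102 in replicate 2. There were 29 in the top 106 of both replicates, 64 in the top 106 of 1 replicate and 13 in neither. Across the full lists, 5901 regions were mutually nearest within 100 bp, 19.7% of a list, against 1945 when replicate 2 was moved by 5000 bp along the chromosome. Their signals had a Spearman rho of 0.16 across regions. Among the 94 IDR peaks found in both replicates rho was 0.06, over peaks selected on pooled signal, which itself joins both replicates. Regions are not independent replicates, so no p is given, and each list has its own signal scale.

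**Figure D1:**
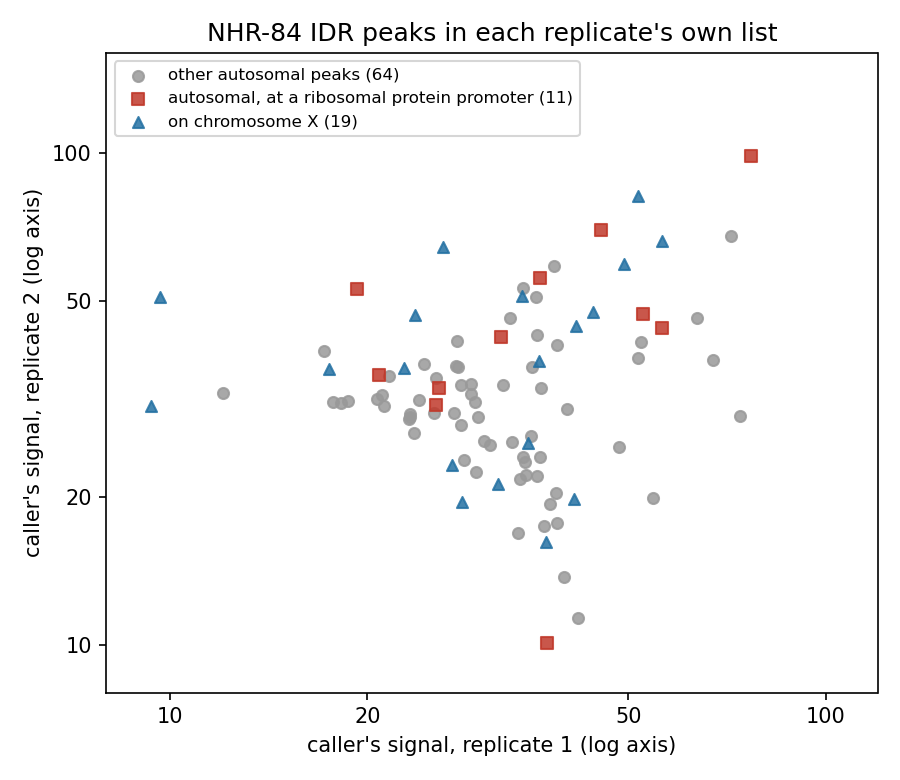
Caller's signal of the IDR peaks in the list of replicate 1 (horizontal, log axis) and of replicate 2 (vertical, log axis), 1 point per peak for the 94 peaks found in both lists. The rpl-3 peak is at the upper right, at 77.1 and 98.7, and the remaining peaks scatter widely (rho 0.06).

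IDR peaks lay at promoters of protein-coding genes more often than lower regions did. The summit of 56 of the 106 peaks (52.8%, Wilson interval 43.4 to 62.1) was between 500 bp upstream and 100 bp downstream of a coding TSS, among them rpl-3, cdc-48.1, tasp-1 and abhd-5.2. Lower pooled regions of the same chromosomes gave 16.9% (one-sided permutation p = 1e-05, the smallest that 100000 draws can give). The share fell with rank, from 33.5% at ranks 107 to 500 to 28.4% at ranks 501 to 1000 and 15.9% at ranks 5001 to 30000. Coding exons held 3 peaks (2.83%) and 24.2% of lower regions, introns 14 peaks (13.2% against 28.1%) and intergenic sequence 21 peaks (19.8% against 26.2%). The 5' UTR class held 2 peaks and the 3' UTR class 1. Annotated 5' ends of many C. elegans genes are trans-splice sites and not transcription starts, so distances to a TSS are approximate.

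**Figure D2:**
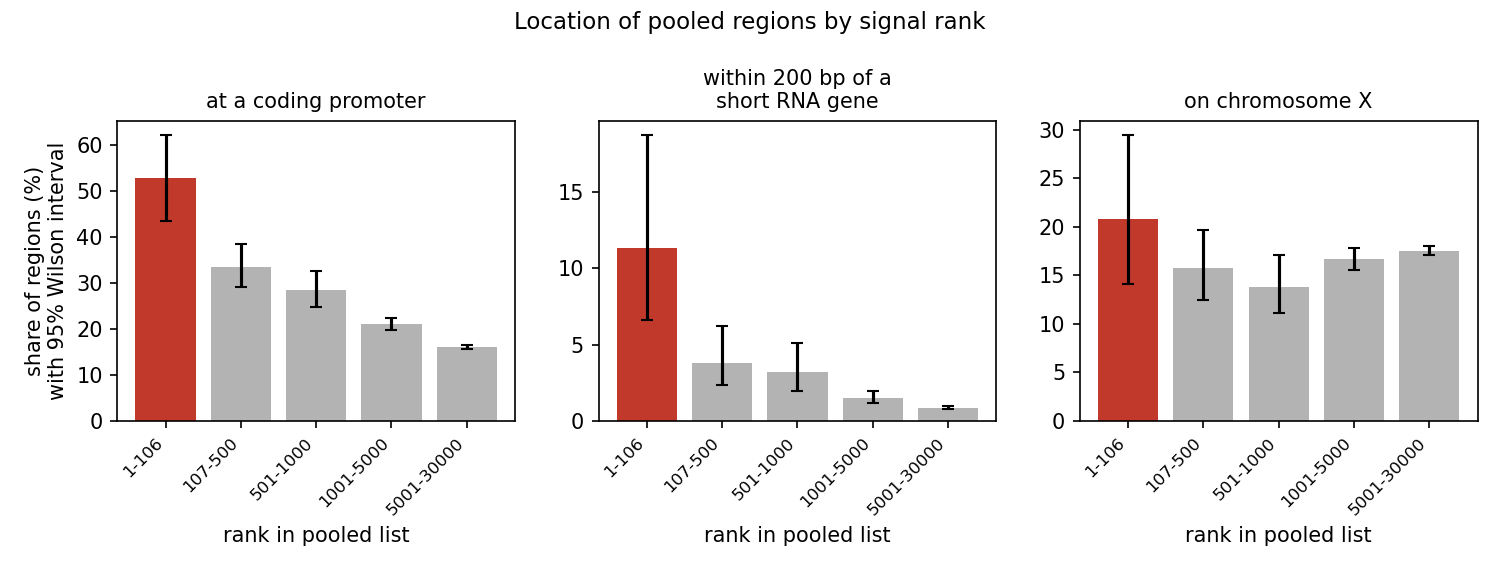
Share of pooled regions (vertical, percent, each panel from 0) at a coding promoter, within 200 bp of a short RNA gene and on X, in 5 bins of signal rank, with 95% Wilson intervals. The IDR peaks (first bar) stand at 52.8% in the first panel and 11.3% in the second, above every lower bin, and their interval on X overlaps those of the lower bins.

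Promoter location differed between X and the autosomes, in a comparison that was not planned. On the autosomes 52 of 84 IDR peaks (61.9%, Wilson interval 51.2 to 71.6) were at a coding promoter, and on X 4 of 22 (18.2%, 7.31 to 38.5), a difference with an odds ratio of 0.137 (two-sided Fisher's exact p = 0.000279). The X share was near the 13.9% of lower X regions (permutation p = 0.364). Of the X peaks, 15 were intergenic, against 6 of the 84 autosomal peaks. The median distance to the nearest coding TSS was 2284 bp on X and 288 bp on the autosomes.

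The number of peaks per chromosome did not differ detectably from that of lower regions. X held 22 peaks (20.8%, Wilson interval 14.1 to 29.4) against 17.3% of lower regions, and chromosomes I to V held 20, 18, 19, 12 and 15 (permutation p = 0.232 over all chromosomes, one-sided p = 0.204 for X).

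Genes for small nuclear and small nucleolar RNAs, which act in splicing and in RNA modification, held peaks far more often than lower regions did. Within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene lay 12 of the 106 summits (11.3%, Wilson interval 6.60 to 18.8), against 1.04% (permutation p = 1e-05, the smallest possible). Of these, 6 were at snRNA genes (5.66% against 0.0768%) and 6 at snoRNA genes (5.66% against 0.299%). Not all were found in both replicates. The peak at F59C6.15 had no region within 100 bp in replicate 2. Those at T11F9.15, Y17G7B.25 and Y53F4B.47 had none in replicate 1, where 98 of all 106 IDR peaks had one. No peak lay at a tRNA gene, where 0 of 106 allows a share of up to 2.83% and lower regions gave 0.66%, so a difference was not detectable. Among the highest were those at sls-2.4 (I, gene 4172206 to 4172315, signal 98.3), sls-2.1 (II, 5844865 to 5844974, 89.3), the snoRNA gene ZK994.7 (V, 8500579 to 8500645, 85.6), sls-2.2 (82.9, named after its value was seen) and the snRNA gene R07E5.16 (III, 10989679 to 10989780, 81.0). Several snRNA genes have near-identical copies, and how reads were placed among copies is not given in the sources used here. Most of the snRNA peaks lay at members of 1 family, sls-2.1, sls-2.2, sls-2.3 (named after its value was seen) and sls-2.4. The peaks at sls-2.2 and sls-2.3 were neighbours on II, with summits at 5543724 and 5544300. The permutation test takes peaks as independent, which such copies are not, so its p may be too small.

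Among 20 gene lists, ribosomal protein genes and snRNA and snoRNA genes passed the test. An IDR peak lay in the promoter window of 12 of the 42 ribosomal protein genes with any pooled region there (28.6%, Wilson interval 17.2 to 43.6), against 0.927% of other genes. The odds ratio was 42.7 (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.5e-13). It was 22.5 with replicate 1 alone and 92.0 against all annotated genes, with the same call. Members came from both subunits, led by rpl-3, rpl-35, rps-19 and rpl-20, and their 12 peaks counted once each were 11.3% of IDR peaks, against 0.127% of lower regions (permutation p = 1e-05, the smallest possible). Of the 12, 4 lay in no other gene's promoter window, with windows of noncoding genes counted too. More than these 4 lay in no other coding gene's window. For snRNA and snoRNA genes the count was 11 of 142 (7.75%, 4.38 to 13.3), with an odds ratio of 8.78 (Fisher's exact test, adjusted p = 2.4e-06) and of 5.44 with replicate 1 alone. Among the 11 were the related genes sls-2.1, sls-2.3 and sls-2.4, while the test takes genes as independent.

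The other lists with any peak had 1 or 2 members with one and did not pass. Translation factors had 2 of 18 (eef-1A.2 and eef-1A.1, signals 88.0 and 65.1, Fisher's exact test, adjusted p = 0.0989), though this list passed with replicate 2 alone (0.0482), with the 53 highest peaks (0.0235) and against all annotated genes (0.0213). Their coding sequences are close copies of each other. Core histones had 1 of 3 (his-37, 65.9, Fisher's exact test, adjusted p = 0.155), heat shock proteins 1 of 6 (the chaperone gene hsp-90, 60.4, 0.244) and the mitochondrial respiratory chain 1 of 16 (cox-5A, 81.2, 0.516; 0.0448 with replicate 2 alone).

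No IDR peak was found in the promoter windows of the other 14 lists. These were nuclear hormone receptors (0 of 66 genes), homeobox genes (17), cuticle collagens (35), cytochrome P450s (11), UDP-glucuronosyltransferases with glutathione S-transferases (23), fatty acid metabolism (29), C-type lectins (32) and tRNA genes (197). Lists of marker genes for intestine (6), hypodermis and seam (9), body wall muscle (15), neurons (26), pharynx (25) and germline (4) also had none. A count of 0 allows a share of up to 4.55% for nuclear hormone receptors and 1.52% for tRNA genes, but up to 75% for the 4 germline genes, so small lists could hold many unseen members. These limits hold for the IDR peaks and this window only. In the window from 2000 bp upstream to 500 bp downstream, 1 of 170 nuclear hormone receptors, 1 of 87 cuticle collagens and 4 of 407 tRNA genes had an IDR peak, with none of these lists past the threshold. Outside both windows, IDR peaks had nhr-88 (2573 bp), nhr-40 (2212 bp) and nhr-21 (514 bp, in an intron) as their nearest coding gene. These were named after their values were seen, and an excess of such peaks was not tested. The 106 highest regions of replicate 1 alone lay at 5 of 214 tRNA genes (odds ratio 2.96, Fisher's exact p = 0.0331, adjusted 0.133) and 1 of 30 pharynx genes. Those of replicate 2 alone lay at 1 of 159 tRNA genes, 1 of 14 pharynx genes and 1 of 76 nuclear hormone receptors, and none of these passed. Genes outside the nuclear hormone receptor list had a share of 1.05%, under the limit of each of these lists, so a lower share was not detectable.

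**Figure D3:**
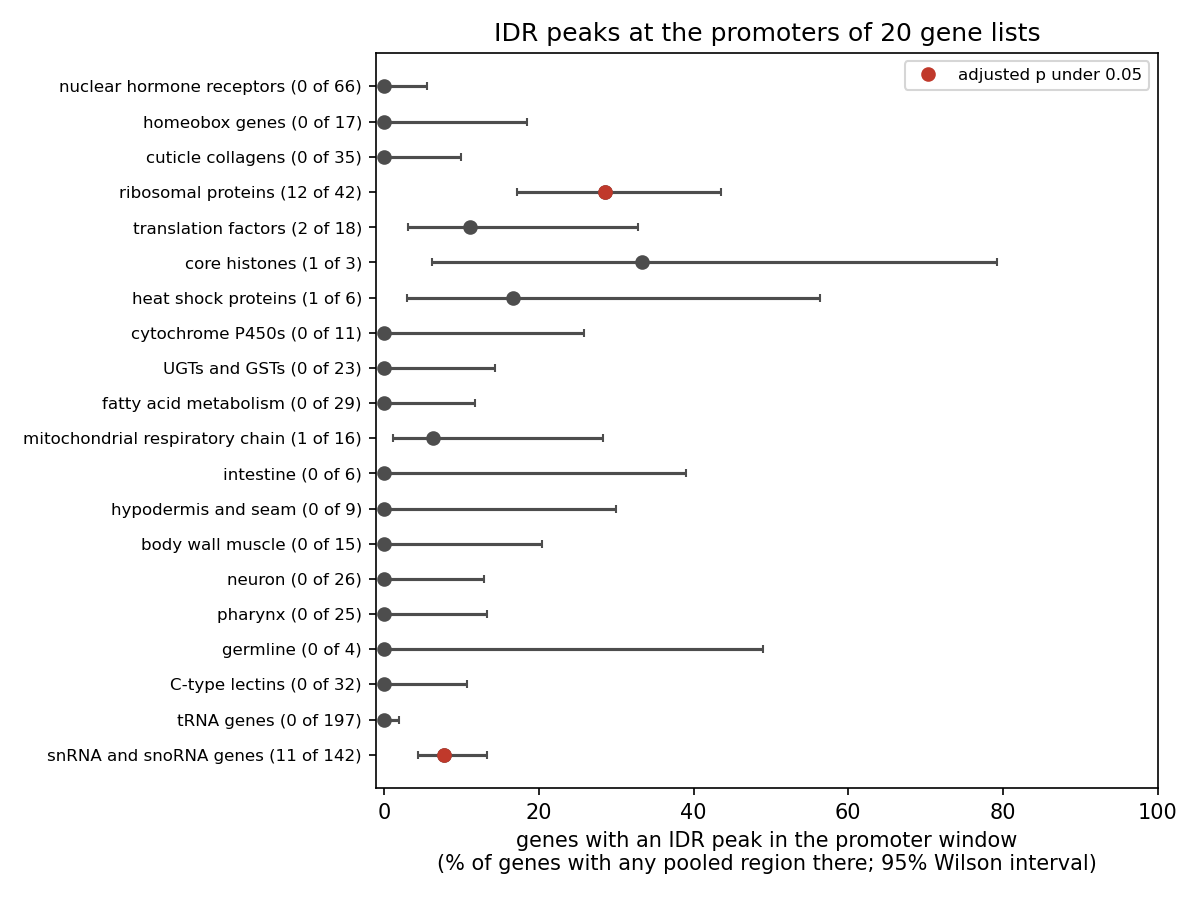
Share of genes with an IDR peak in the promoter window (horizontal, percent of the genes of the list with any pooled region there) for 20 lists, with 95% Wilson intervals. Ribosomal proteins (12 of 42) and snRNA and snoRNA genes (11 of 142), in red, have an adjusted p under 0.05.

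The nhr-84 gene itself (WBGene00003674, V, 15876732 to 15879608, minus strand) had no IDR peak at its promoter. The single pooled region there ranked 7562, with a signal of 24.0. The surrounding 20 kb on either side held 40 pooled regions, against a median of 13 and a maximum of 42 in 10000 random windows of the same size (one-sided permutation p = 0.0003). Of the 40, 10 were among the 1000 highest regions of the genome, and 33 lay outside coding promoter windows. The highest was an IDR peak of rank 62 in cgt-1 (V, 15887119 to 15887422, signal 58.5), 7663 bp from the nearest nhr-84 TSS, a gene named here after its value was seen. This peak ranked 23 in replicate 1 and 7736 in replicate 2. Replicate 1 alone had 40 regions in the window and replicate 2 had 42. The transgene carries nhr-84 sequence, so its copies and the endogenous gene cannot be separated in these lists.

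**Figure D4:**
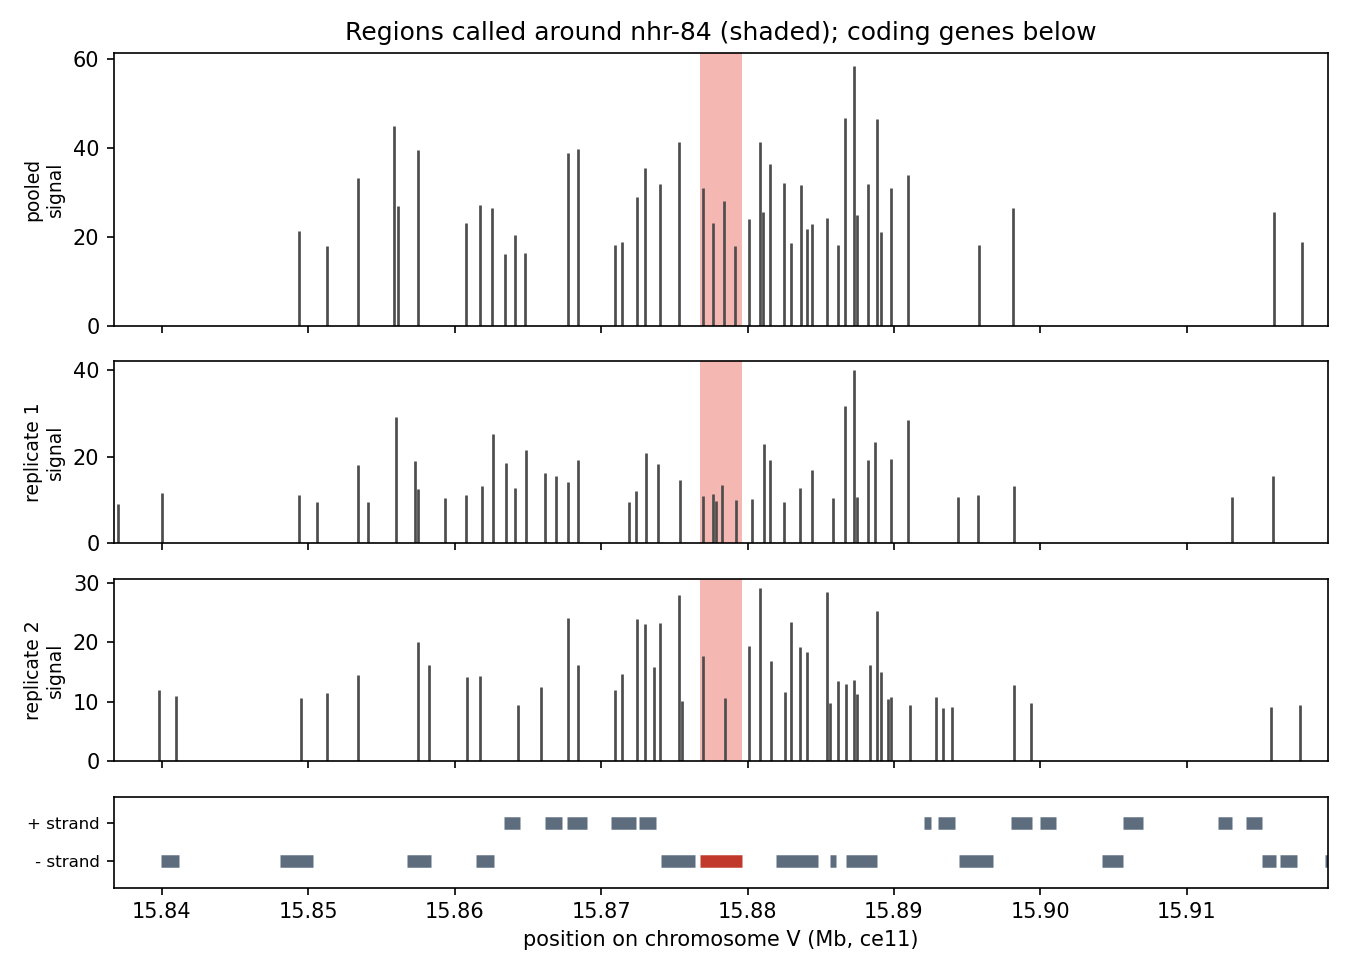
Regions called on chromosome V around nhr-84 (shaded; horizontal axis in Mb) in the pooled list and in each replicate, with the height of each line giving the caller's signal on that list's own scale and coding genes drawn by strand below. Pooled regions are densest from 15878170 to 15893169, where each of 3 bins of 5 kb holds 5 or 8, and sparse to the right of it.

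Sequence at the IDR summits was richer in G and C and held 1 of 7 fixed words more often. GC content within 50 bp of the summit was 45.7% ± 7.99 (SD over 106 peaks), against 36.8% ± 7.88 (29894 lower regions, permutation p = 1e-05, the smallest possible). This test of GC content was not planned. GAGAGA was found at 19 peaks (17.9%, Wilson interval 11.8 to 26.3), against 9.21% in lower regions matched on GC (permutation test, adjusted p = 0.0281). These regions were not matched on promoter location, which differed between IDR peaks and lower regions. AGGTCA, the half-site bound by many nuclear receptors, was found at 4 peaks (3.77%, 1.48 to 9.30) against 2.92% (permutation p = 0.375, adjusted 0.524). AGTTCA, GTAAACA, TGACTCA, CACGTG and GATAA did not pass either, with adjusted permutation p from 0.349 to 1.

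The list on build ce10 held 117 IDR peaks. Of the 106 ce11 peaks, 105 had a ce10 peak on the same chromosome with a signal within 0.1%. The 11 further ce10 peaks had signals from 50.6 to 51.7, and the 11 ce11 pooled regions directly below the IDR peaks had the same range, so the lists differ mainly in how far down the ranking they reach.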

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

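Of 55 alternatives over 12 results, 54 kept the direction and the side of the threshold or, where there was no test, stayed within 1.5 times the main count or the 95% interval of the rank correlation, or kept the highest nhr-84 region at or above percentile 95. The exception was the number of gene lists past the threshold, 2 in the main test. Leaving out 1 replicate gave 2 to 4, with translation factors and the mitochondrial respiratory chain added at 4, without replicate 1; the cause was not tested. It was 3 with the 53 highest peaks and against all annotated genes, where translation factors passed too. The IDR peak count was 117 on ce10, and the overlap of the replicates fell to 12.8% with the 1000 highest regions. Ribosomal proteins and snRNA and snoRNA genes passed under each alternative run for them. The promoter share was 50% without replicate 1 and 39.6% without replicate 2, and 65.1% and 73.6% in the wider windows, each above its background. Backgrounds of coding genes or of ranks down to 1000, and autosomal peaks only, were chosen after seeing the data and changed no call. A stricter IDR score was planned and not run, since the score column is 0 for every peak. No paired analysis was possible because there is 1 group. Depth is unknown, so what it limits was not tested.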

Other observations

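The tests on base composition, on promoter windows shared with another gene, on the transgene and the gene's own promoter, and on other abundantly transcribed genes were chosen only after the result was seen. The count of regions around nhr-84 was planned, while the word on X was noticed in these data and then tested on them, and the explanations offered for all 3 patterns are hypotheses. The design has 1 group and gives no biological contrast to set against the technical explanations.

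Some X peaks shared sequence words. Among 2080 words of 6 bases searched as exploration, CCTGCG was found within 100 bp of 9 of 22 X summits (40.9%) against 2.67% in lower X regions matched on GC (permutation test, adjusted p = 0.0026). On the autosomes GAGCGC, 1 of several words with the lowest adjusted p, was at 18 of 84 summits (21.4% against 4.10%, permutation test, adjusted p = 0.00297). CGCGCA was more frequent in both sets, at 10 of 22 X summits (45.5% against 4.64%, permutation test, adjusted p = 0.0026) and 12 of 84 autosomal ones (14.3% against 3.999%, adjusted 0.0116).

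The longer word TCGCGCAGGG, which holds CGCGCA, lay within 100 bp of 7 of 22 X summits (31.8%, Wilson interval 16.4 to 52.7), against 1 of 5169 lower X regions and 0 of 84 autosomal summits. Of these 7 X peaks, 0 were at a coding promoter, 5 were intergenic and 6 lay over 2000 bp from the nearest coding TSS. They therefore form part of the difference in promoter location between X and the autosomes. Ranks in replicates 1 and 2 were 11 and 2 for the peak nearest to W02H3.3, 13 and 7 for gtr-1, and 181 and 6 for xol-1. They were 334 and 17 for Y41G9A.17, 20 and 1090 for F22H10.2, and 25965 and 13 for cest-16. The ins-39 peak ranked 42 in replicate 1 and had no region within 100 bp in replicate 2. The word was at 4 of 24 X regions (16.7%) in the top 106 of replicate 1 and 8 of 21 (38.1%) in those of replicate 2. Base composition of the X peaks does not account for it: in lower X regions matched on GC its share was 0.0302%, and in 1000 draws of 22 of them no word of 10 bases was at more than 5 regions (permutation p = 0.001, the smallest possible). A sequence preference of the assay for the word itself stays open. With at most 1 mismatch, 10 of 21 X regions holding it were IDR peaks against 1 of 45 autosomal ones (two-sided Fisher's exact p = 1.5e-05). But the word was picked from the X peaks, and exact matches were 8 on X and 1 on the autosomes, so this comparison decides nothing. The 44 lower autosomal regions with at most 1 mismatch had a median rank of 13768.5 against 15001. Their mean rank was 14612.1 (permutation p = 0.385 of the mean rank), which shows no such preference and does not exclude one. The word resembles the motif known for recruitment sites of the dosage compensation complex on X, and such sites may be the source. The 11 lower X regions with at most 1 mismatch had a median rank of 2754 against 15321 for other X regions. The test was on their mean rank, 10713.9 (one-sided permutation p = 0.0395), so some of the 11 ranked far down. The result rests on 11 regions. Whether NHR-84 is bound there, or these sites give signal in any ChIP, stays open too, since no other ChIP was analysed here.

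Regions crowded around nhr-84 on chromosome V. Many promoters in the window do not account for it, since the count lay at percentile 100 of 466 random windows with at least as many coding TSS. In the pooled list, binding of NHR-84 to its own promoter was not the whole cause, since the highest region lay 7663 bp from the nearest TSS. That region ranked 23 in replicate 1 and 7736 in replicate 2, so the distance of 7663 bp rests on replicate 1. In replicate 2 alone the highest region in the window (signal 29.2) had its summit at 15880840, much closer to nhr-84. It still lay outside the gene's promoter window and beyond the bound of 1 kb set for this explanation. A pooled region with its summit at 15880861 lay 1253 bp from the TSS. Extra copies of the locus carried by the integrated transgene may contribute, but in the pooled list the test set for it was met on 1 side only. Of the 3 nearest bins of 5 kb, 3 on the right and 1 on the left exceeded the genome's 95th percentile of 4 regions. The lower count, 1, decides. The left bins held 4, 5 and 4 regions, so those that failed lay at the cutoff itself. The same bins held 6, 4 and 5 regions in replicate 1 and 3, 5 and 5 in replicate 2, so the outcome on the left is not firm. Farther out, 0 of 14 bins exceeded the percentile. The bins between, left out of the 14, held 4 and 3 regions on the left and 2 and 0 on the right. Each of the 6 near bins holds a coding promoter, so the part of the test that needed bins without one could not be run, and extra copies cannot be told apart from other causes here.

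Ribosomal protein promoters held 12 of the 106 peaks. Peaks between 2 divergent genes counted for both were not tested by counting each peak once (permutation p = 1e-05, the smallest possible), since the 12 genes have 12 different peaks, but promoter windows shared with another gene are not the whole cause: the parts in no other gene's window held 4 peaks (3.77%) against 0.0665% of lower regions (permutation p = 1e-05). For unspecific signal at highly transcribed genes, 1 of 5 other lists of such genes passed (snRNA and snoRNA genes), while tRNA genes had no peak (0 of 197). At least 2 passing lists would have been needed, and 0 would have argued against it. These bounds were set after the result was seen, so the number of passing lists decides nothing. That number was 2 or more under 3 of 8 alternatives and reached 3 with replicate 2 alone. Unspecific signal and binding by NHR-84 therefore cannot be told apart at these promoters, and a ChIP without the tag was not analysed here.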
